A study of Mus musculus with 12 samples.

How the data were processed

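Gene expression was measured on Affymetrix mouse genome arrays in embryonic mouse gonads at E11.5, the day around which the bipotential gonad takes the testis or ovary path. Embryos came from crosses of Cbx2 heterozygotes and were staged by their tail somites. Gonadal cells were captured by laser microdissection from 30 µm frozen sections, guided by GATA4 immunostaining and tissue form. Material of 2 or 3 individuals was pooled for each array. P-values for single genes and for array measures therefore rest on the spread between such pools and not between embryos. Tests of a gene list against all other genes, and permutations over genes or their signs, draw on the spread between genes. From each pool 15 ng of total RNA went through 2-cycle amplification and biotin labelling.

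The deposited values were log2 values made by the authors with RMA, which corrects background, applies quantile normalization across arrays and summarises the probes of each probe set. The submitters' processing notes name Affymetrix Expression Console, RMA and affy, whose versions are not given in the sources used here. The values ran from 2.4 to 15, and array medians lay near 5.9, so they were used as given, with no further transformation, centring or filter on low values. Raw scans were not analysed here. The labels give no scan date, batch or sequencing-like depth, and for arrays the number of arrays limits the precision.

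The 12 arrays formed 4 groups of 3, crossing genotype (knockout, KO, or wild type, WT) with chromosomal sex (XX or XY). Groups were taken from the genotype labels and sample titles. The source description of the WT samples names the KO XX group instead, which contradicts their titles and genotype field, so KO and WT stand for arrays labelled so in the latter. Of 45101 probe sets, 64 were controls, 34945 were assigned to a single gene, 932 to several genes and 9160 to none. Of the single-gene probe sets, 34741 were matched by gene identifier to current symbols, and no symbol had to be changed. A gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes, 9010 of them with several probe sets.

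Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes at default settings, 4 group means and 8 residual degrees of freedom. The 6 contrasts were KO against WT in XY, in XX and averaged over both sexes, XY against XX in WT and in KO, and the difference of the KO effect between XY and XX (the interaction). Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Log2 fold changes are given ± standard error and group means ± standard deviation, with n = 3 pools per group. For the control measures, which are single values per array, groups were compared by exact permutation tests, whose smallest possible two-sided p was 0.1 at 3 against 3.

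Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. The 23 lists covered early gonad factors, testis, ovary and steroidogenic genes, Polycomb repressive complex (PRC) subunits, Hox and other patterning genes, proliferation, cell cycle inhibitors, p53 targets, retinoic acid, stress response, Y-linked and X-inactivation genes. Further lists held markers of germ cells, mesonephros, coelomic epithelium, adrenal primordium, endothelium, erythroid cells, macrophages and neural cells. For each list the genes past the threshold over all genes are given beside those adjusted over the list alone.

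The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Named genes were Cbx2, Xist and the Y-linked genes, and the 10 largest changes each way in the KO against WT contrasts (5 each way in the others). These had to pass the test with every array of 1 group above every array of the other, except in the interaction. Up to 4 members per list with the smallest p were added, and any member of the early gonad, testis, ovary, germ cell and PRC1 lists. Predicted and unnamed genes were counted but not named.

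The steps were tested on simulated data with the study's layout and 18193 genes, 100 of them shifted by a log2 fold change of 1 and 100 by 2. At a shift of 1 the share recovered was 90% for KO against WT in XY, 88% in XX and 97% over both sexes, 88% for XY against XX in WT, 86% in KO and 62% for the interaction. The simulated noise was independent between genes, so no array deviated as a whole. In the data WT XX replicate 1 did, so these shares do not give the power of the real comparisons with WT XX. Alternatives covered the normalization, the low-value filter, the choice of probe set, the variance prior, array weights, a replicate block, the groups in the fit, the threshold and leaving out each array in turn. Covariates for RNA integrity (the Gapdh 3' minus 5' control difference) and for hybridisation spike-in level were added after the data were seen.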

Results

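Expression profiles were collected from 12 pools of laser-captured gonadal cells of E11.5 mouse embryos, 3 each from KO XX, KO XY, WT XX and WT XY embryos. Cbx2 encodes a chromobox subunit of PRC1, the Polycomb complex that holds developmental genes silent. The design asks how its loss alters transcription in XX and XY gonads while the sexes begin to diverge. Xist, the RNA that coats the inactive X chromosome, had group means of 12.65 ± 0.10 in WT XX and 12.80 ± 0.13 in KO XX, against 6.03 ± 0.05 in WT XY and 5.95 ± 0.12 in KO XY (log2, SD, n = 3). The Y-linked translation factor gene Eif2s3y lay at 3.30 ± 0.16 in WT XX and 3.62 ± 0.12 in KO XX, and at 9.60 ± 0.21 in WT XY and 9.85 ± 0.26 in KO XY. In every array both genes matched the sex of its label. The testis-determining gene Sry could not be followed, since its probe set gave means from 5.86 in WT XX to 6.0 in KO XY and no difference between the sexes passed the test. The Y-linked genes Usp9y and Zfy2 likewise stayed low in all groups, and Ddx3y and Zfy1 had no probe set assigned to them alone.

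Cbx2 signal was higher in arrays labelled KO. Its brighter probe set rose by 0.52 ± 0.12 in XY (adjusted p = 0.00869) and by 0.74 ± 0.12 in XX (adjusted p = 0.000645), with group means of 9.45 ± 0.12 in KO XY, 8.93 ± 0.12 in WT XY, 9.34 ± 0.11 in KO XX and 8.60 ± 0.16 in WT XX. The call for Cbx2 in XY ended without WT XY replicate 3 (adjusted p = 0.0507) and with the RNA-integrity covariate (adjusted p = 0.111), in a range from 0.000383 to 0.111 over the alternatives. The second Cbx2 probe set lay between 3.87 and 4.09 in all groups. Which part of the gene the allele lacks is not given in the sources used here, so the probe sets decide nothing about the genotype. All KO directions rest on the genotype labels and would turn if these were exchanged. The source description of the WT samples contradicts the labels. Yet it names the KO XX group for the WT XY arrays too, against their Xist and Eif2s3y. Exchanged labels would also leave wild-type XY gonads without the XY rise of the testis gene Sox9. Its values were 8.558 to 8.964 in arrays labelled WT XY and 5.703 to 6.138 in those labelled KO XY. They argue against an exchange, which Cbx2 itself does not settle.

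Genotype separated the arrays more than sex did. The first principal component carried 53.3% of the variance and placed the KO arrays between -33.29 and -23.51 and the WT arrays between 14.09 and 37.38. WT XX replicate 1 stood apart from its group, with a mean correlation across genes of 0.988 with WT XX replicates 2 and 3 and of 0.995 with the WT XY arrays. WT XX replicates 2 and 3 in turn lay at 28.46 and 29.2 on the second component. The next highest array there, KO XX replicate 1, lay at 11.64. The Gapdh 3' minus 5' difference, which grows as RNA degrades or as amplification shortens the transcripts, was 4.91 ± 0.12 in KO XY, 4.13 ± 0.38 in WT XY, 4.05 ± 0.22 in KO XX and 4.31 ± 0.45 in WT XX.

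**Figure D1:**
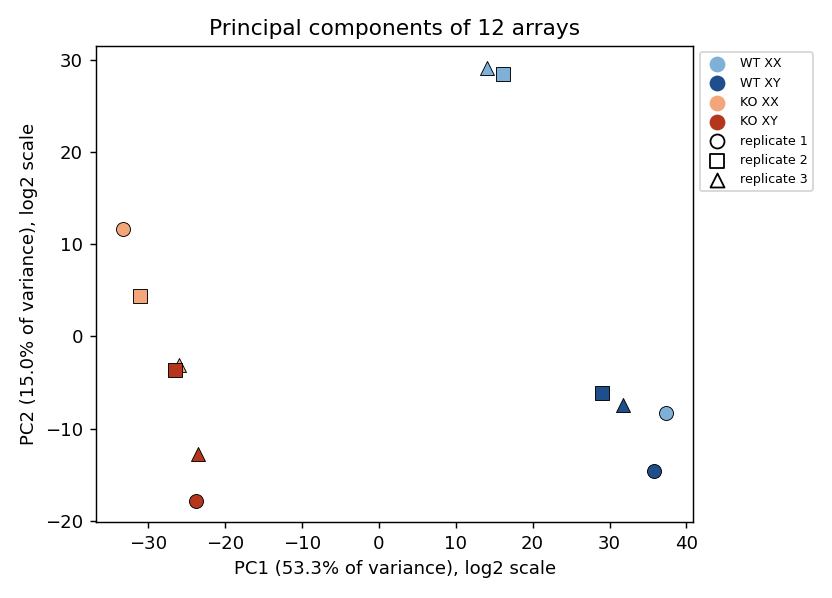
Positions of the 12 arrays on the first and second principal components of 18193 genes (log2 scale), coloured by group, with a marker for each replicate number. KO arrays lie between -33.29 and -23.51 on the first component and WT arrays between 14.09 and 37.38, and WT XX replicate 1 lies with the WT XY arrays.

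Knockout and wild type were first compared in XY gonads, to ask what the loss of Cbx2 changes where a testis would form. Sox9, the transcription factor that directs Sertoli cell fate, fell by 2.77 ± 0.18 (adjusted p = 2.24e-07), from 8.72 ± 0.22 in WT XY to 5.95 ± 0.23 in KO XY. Other genes of the testis pathway fell with it. The secreted cerebellin Cbln4 changed by -3.86 ± 0.25, the activin and inhibin subunit Inhbb by -3.64 ± 0.23, the cystatin-related Cst9 by -3.05 ± 0.35 and the transcription factor Dmrt1 by -2.0 ± 0.28. Amh, the Müllerian inhibitor that appears later in Sertoli cells, had a value of -0.06 ± 0.11 (adjusted p = 0.782), and the Sertoli growth factor Fgf9 one of 0.12 ± 0.36 (adjusted p = 0.890). Of 22 measured testis-pathway genes, 13 fell and none rose (14 fell adjusted over the list alone), and the list passed camera (adjusted p = 7.31e-12, and adjusted p = 0.0499 with an estimated correlation, which became adjusted p = 0.0904 without WT XX replicate 1).

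The largest decreases in XY were in Akr1cl, an aldo-keto reductase (-5.45 ± 0.24), Aldh1a1, a retinaldehyde dehydrogenase (-4.90 ± 0.29), and Ereg, an epidermal growth factor family ligand (-4.43 ± 0.23). Sphkap, Cpa1, Sybu, Nrn1, Tph2, Vav3 and Aldh1a7 followed with values from -4.13 to -3.88. The largest increases were in the synaptic adhesion gene Lrrtm4 (3.29 ± 0.24), the matrix gene Ecm1 (3.14 ± 0.16) and the cytokine Il33 (2.69 ± 0.27), ahead of Adamtsl4, Tgm2, Nefm, Bmper, Efemp1, Lratd1 and the epithelial keratin Krt19 (2.41 ± 0.14). In each of these 20 genes every KO XY array lay beyond every WT XY array.

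Further groups moved in XY gonads. Of 18 ovary-pathway genes 8 fell and 1 rose (8 and 2 adjusted over the list alone), among them the activin antagonist Fst (-3.35 ± 0.29) and the pregranulosa factor Runx1 (-2.68 ± 0.24). Camera gave adjusted p = 6.66e-05, and adjusted p = 0.0636 with an estimated correlation. Of 33 Hox genes 11 rose and none fell (12 and 1 adjusted over the list alone), including Hoxc8 (1.56 ± 0.21) and Hoxc5 (1.06 ± 0.18), with adjusted p = 7.83e-05, and adjusted p = 0.219 with an estimated correlation. Coelomic epithelium markers rose in 6 of 10 cases and fell in 1, Aldh1a1 (the same adjusted over the list alone), with adjusted p = 0.00677, and adjusted p = 0.0877 with an estimated correlation. Endothelial markers fell in 11 of 16 cases (13 adjusted over the list alone), with adjusted p = 2.70e-08, while macrophage markers rose in 4 of 13 (5 adjusted over the list alone, and 1 to 5 with single arrays left out), with adjusted p = 0.00599. With an estimated correlation these were adjusted p = 0.219 and adjusted p = 0.503. Immediate early and heat shock genes fell in 5 of 14 cases and rose in 1 (7 and 1 adjusted over the list alone), with adjusted p = 0.0199, and adjusted p = 0.219 with an estimated correlation.

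By limma, 2421 of 18193 genes changed in XY, 1193 upward and 1228 downward, of which 293 and 387 did so at least 2-fold. Groups did not overlap in 6719 genes (36.9%, where chance gives 10%). The Gapdh difference was higher in KO XY than in WT XY by 0.786 (exact permutation p = 0.1, the smallest possible), and with it as a covariate, added after the data were seen, 780 genes passed (301 upward and 479 downward), 742 of them among the 2421. Without WT XY replicate 1 the number was 1598.

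The same comparison in XX gonads asked whether the change needs a Y chromosome. Fst, which takes part in ovary formation, fell by 4.28 ± 0.29 (adjusted p = 3.72e-07), from 10.02 ± 0.76 in WT XX to 5.74 ± 0.15 in KO XX. Further ovary-pathway genes fell, with values of -3.23 ± 0.32 for the epithelial gene Sprr2d, -2.94 ± 0.24 for Runx1, -2.87 ± 0.18 for the signalling ligand Bmp2, -2.24 ± 0.21 for the Wnt-associated receptor Lgr5 and -1.06 ± 0.18 for the ovarian transcription factor Foxl2. Of 18 genes on this list 10 fell and 1, the Wnt receptor Fzd1, rose (10 and 2 adjusted over the list alone), with adjusted p = 2.14e-06 by camera, and adjusted p = 0.0267 with an estimated correlation. Testis-pathway genes fell too, 8 of 22 with 1 higher (12 and 1 adjusted over the list alone), with adjusted p = 5.50e-06, and adjusted p = 0.118 with an estimated correlation. Inhbb changed by -3.42 ± 0.23, Cbln4 by -2.17 ± 0.25 and Dmrt1 by -2.15 ± 0.28, whereas Sox9 had a value of 0.03 ± 0.18 (adjusted p = 0.937). The list's higher member was Fgf9, at 1.26 ± 0.36 (adjusted p = 0.0294), whose call ended without any of KO XX replicates 1 and 3 and WT XX replicates 1 and 3, at up to adjusted p = 0.120, in a range from 0.000974 to 0.120 over the alternatives.

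The largest XX decreases were again in Akr1cl (-4.64 ± 0.24) and Aldh1a1 (-4.49 ± 0.29), with Sphkap, Nrn1, Aldh1a7, Ereg, Gbp2b, Tph2 and Cpa1 between -4.18 and -3.46. The largest increases were in Lrrtm4 (3.32 ± 0.24), Ecm1 (2.88 ± 0.16), Il33 (2.77 ± 0.27) and Krt19 (2.71 ± 0.14), ahead of Ppargc1a, Sema3d, Tgm2, Id4, Negr1 and Ngp. Coelomic epithelium markers rose in 6 of 10 cases and fell in 1 (7 and 1 adjusted over the list alone), with adjusted p = 0.000152, and adjusted p = 0.0267 with an estimated correlation. Among them the uroplakin Upk1b gained 1.86 ± 0.18 and the mesothelial transcription factor Bnc1 1.68 ± 0.17. Hox genes rose in 12 of 33 cases (13 adjusted over the list alone), with adjusted p = 0.000520, and adjusted p = 0.339 with an estimated correlation.

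PRC1 subunits rose in 4 of 18 cases (2 to 4 with single arrays left out) and fell in 1 (5 and 1 adjusted over the list alone). The stem-cell regulator Bmi1 led the increases (1.33 ± 0.14), which include Cbx2 itself. The camera result of the list was adjusted p = 0.0124, adjusted p = 0.339 with an estimated correlation, and adjusted p = 0.0545 without WT XX replicate 2. Endothelial markers fell in 9 of 16 cases (12 adjusted over the list alone, 2 to 10 with single arrays left out and 5 without WT XX replicate 1), including Sox17, a regulator of arterial endothelium (-1.44 ± 0.22), with adjusted p = 1.51e-05, and adjusted p = 0.339 with an estimated correlation. Macrophage markers rose in 3 of 13 cases (5 adjusted over the list alone, and 0 to 4 with single arrays left out), with adjusted p = 0.00180, adjusted p = 0.514 with an estimated correlation, and adjusted p = 0.0691 without KO XX replicate 1.

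By limma, 2493 genes changed in XX, 1510 upward and 983 downward, of which 319 and 300 did so at least 2-fold. The excess of increases depended on the processing, with 1224 upward and 1170 downward after repeated quantile normalization, 1595 and 863 after centring on array medians and 1287 and 1053 with the mean of all probe sets of a gene. Groups did not overlap in 4841 genes (26.6%, where chance gives 10%). The Gapdh difference had a KO minus WT value of -0.258 in XX (exact permutation p = 0.4). With it as a covariate, added after the data were seen, 3175 genes passed. A fit of the XX arrays alone gave 1532 genes.

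Across the sexes the changes ran together. Of the genes higher in KO, 833 were shared by XX and XY, where independent lists would share 99. Of those lower in KO 707 were shared, where 66.4 would be. The lists are not fully independent, since both come from the same fit with a shared spread per gene. Some overlap beyond these numbers is therefore built in. A single gene changed in opposite directions. Across all genes the effects in XY and XX, which share no array, had Pearson's r = 0.825 and Spearman's rho = 0.601, although genes are not independent replicates.

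**Figure D2:**
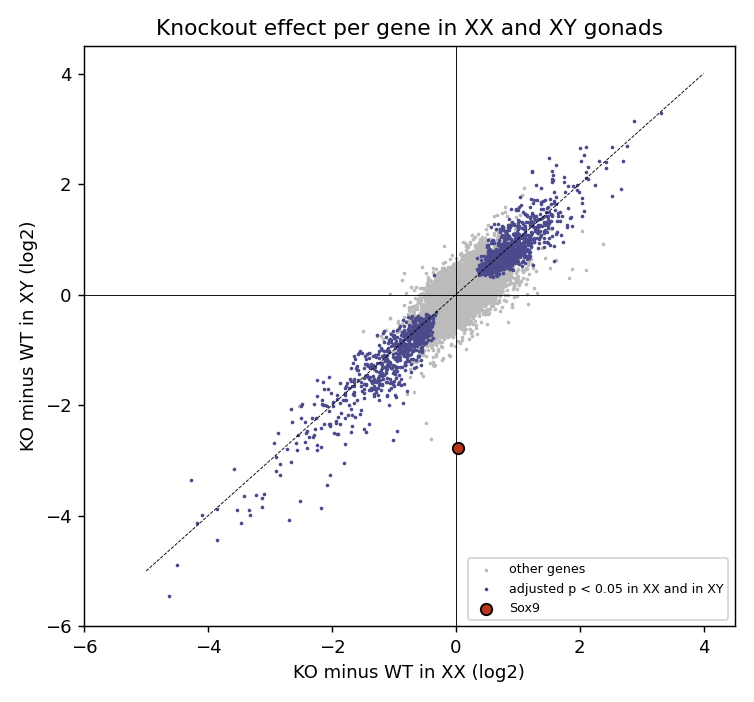
KO minus WT in XX (horizontal, log2) against KO minus WT in XY (vertical, log2) for 18193 genes, with genes past the test in both sexes in dark blue and a dashed line of equality. Effects follow the line (r = 0.825), and Sox9 lies apart at 0.03 in XX and -2.77 in XY.

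Averaged over both sexes, factors that build the early gonad changed in both directions. Gadd45g, needed for timely Sry expression, changed by -3.48 ± 0.12, the nuclear receptor genes Nr0b1 by -2.23 ± 0.18 and Nr5a1 by -2.19 ± 0.12, and the LIM-homeobox gene Lhx9 by -1.08 ± 0.12. Gata4 had -1.45 ± 0.12 (adjusted p = 4.13e-07) on its brighter probe set and -0.28 on the other (adjusted p = 0.0557). GATA4 staining guided the capture, so Gata4 is not an independent readout. The insulin-family receptors Insr (0.95 ± 0.12) and Igf1r (0.76 ± 0.10) and the transcription factor Tcf21 (0.76 ± 0.12) rose. Wt1, which marks the gonadal ridge, had -0.15 ± 0.07 (adjusted p = 0.170) and Emx2 -0.21 ± 0.10 (adjusted p = 0.153). In all, 5 of 17 early gonad factors rose and 6 fell (8 and 6 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.473).

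Testis-pathway genes fell in 15 of 22 cases with none higher (15 and 1 adjusted over the list alone), with adjusted p = 7.13e-10. Ovary-pathway genes fell in 10 of 18 and rose in 1 (10 and 2 adjusted over the list alone), with adjusted p = 1.27e-05. Coelomic epithelium markers rose in 6 of 10 and fell in 1 (the same adjusted over the list alone), with adjusted p = 0.00109. These 3 lists each held at adjusted p = 0.0407 with an estimated correlation. Krt19 gained 2.56 ± 0.10, Upk1b 1.63 ± 0.13 and Bnc1 1.5 ± 0.12, while Aldh1a1 changed by -4.70 ± 0.20.

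Hox genes, which set position along the body, rose in 13 of 33 cases and fell in 1 (14 and 1 adjusted over the list alone), with Hoxc8 at 1.22 ± 0.15 and Hoxc5 at 1.13 ± 0.12. Their camera result was adjusted p = 7.58e-05, and adjusted p = 0.219 with an estimated correlation. PRC1 subunits rose in 6 of 18 cases and fell in 1 (7 and 1 adjusted over the list alone). Bmi1 had 1.09 ± 0.10 and Scmh1 -0.55 ± 0.09, and the increases include Cbx2 itself (0.633 ± 0.08). The list's adjusted p = 0.0373 became adjusted p = 0.440 with an estimated correlation, and was lost without any of KO XX replicate 3, KO XY replicate 1, WT XX replicates 2 and 3 and WT XY replicate 1, at up to adjusted p = 0.0793. PRC2 subunits rose in 4 of 11 cases (5 adjusted over the list alone, 1 to 5 with single arrays left out and 2 without WT XX replicate 1). As a list they missed the threshold (adjusted p = 0.0686, but 0.0394 without KO XY replicate 3 and 0.145 without WT XX replicate 1).

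Endothelial markers fell in 13 of 16 cases (the same adjusted over the list alone), with Sox17 at -1.35 ± 0.16 and the sialomucin Emcn at -0.97 ± 0.13, and with adjusted p = 1.31e-07, and adjusted p = 0.219 with an estimated correlation. Macrophage markers rose in 6 of 13 cases (8 adjusted over the list alone), with the complement gene C1qb at 1.11 ± 0.19, and with adjusted p = 0.000762, and adjusted p = 0.440 with an estimated correlation. Immediate early and heat shock genes fell in 6 of 14 cases and rose in 1 (the same adjusted over the list alone). The growth-response factor Egr1 changed by -1.22 ± 0.16, the chaperone Hspa1b by -0.86 ± 0.10 and Jun by 0.85 ± 0.09. This list had adjusted p = 0.0282, adjusted p = 0.219 with an estimated correlation, and adjusted p = 0.0534 without WT XX replicate 3.

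**Figure D3:**
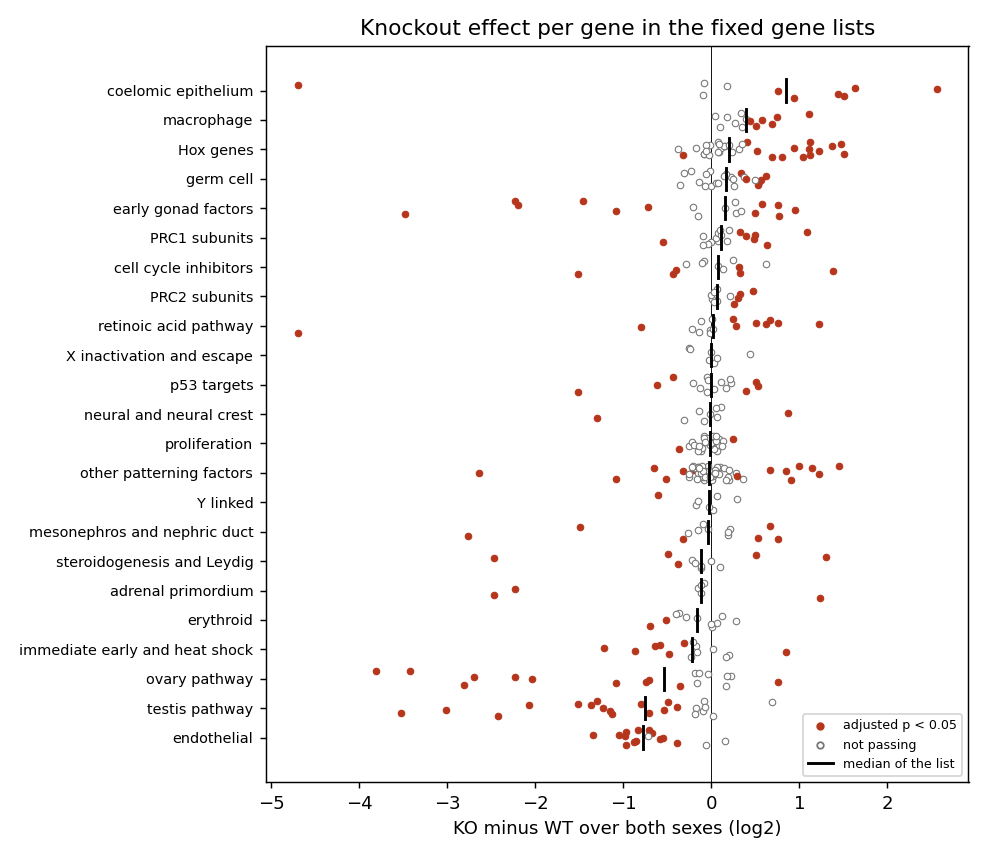
KO minus WT over both sexes (log2) for each measured gene of the 23 lists, filled where adjusted p is under 0.05, with a black bar at the median of the list. Medians run from -0.78 for endothelial markers to 0.85 for coelomic epithelium markers.

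The other lists did not pass camera. Germ cell markers rose in 6 of 23 cases (7 higher and 1 lower adjusted over the list alone, and 3 to 7 higher with single arrays left out), including the RNA helicase Ddx4 (0.62 ± 0.17) and the germline regulator Prdm14 (0.57 ± 0.12), with adjusted p = 0.0911. Without KO XY replicate 3 or WT XY replicate 1 the list passed, at as low as adjusted p = 0.0333, and so it did with the RNA-integrity covariate (adjusted p = 0.0295). Adrenal genes had 1 higher and 2 lower of 7 (the same adjusted over the list alone, adjusted p = 0.0740), with the corticotropin receptor Mc2r at 1.24 ± 0.19. Steroidogenic genes had 2 higher and 3 lower of 11 (2 and 5 adjusted over the list alone, adjusted p = 0.318), with the side-chain cleavage enzyme Cyp11a1 at -2.47 ± 0.16. Mesonephros markers had 3 higher and 3 lower of 13 (the same adjusted over the list alone, adjusted p = 0.693), with the calcium-binding Calb1 at -2.77 ± 0.20. Retinoic acid genes had 7 higher and 2 lower of 16 (the same adjusted over the list alone, adjusted p = 0.428), with the receptor Rarb at 1.22 ± 0.12. Other patterning factors had 8 higher and 6 lower of 54 (the same adjusted over the list alone, 3 to 5 lower with single arrays left out, adjusted p = 0.975), with Msx1 at -2.64 ± 0.14 and Tbx18 at 1.45 ± 0.13.

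Cell cycle inhibitors had 3 higher and 3 lower of 13 and p53 targets 3 and 3 of 16, each the same adjusted over the list alone and each with adjusted p = 0.975, with Cdkn2c at 1.38 ± 0.09 and Cdkn1a at -1.51 ± 0.12. With single arrays left out 1 to 3 of the inhibitors and 3 to 5 of the p53 targets were higher. Proliferation genes had 1 higher and 1 lower of 27 (none adjusted over the list alone, adjusted p = 0.682), and erythroid genes 2 lower of 11 (2 adjusted over the list alone, 0 to 3 with single arrays left out, adjusted p = 0.368). Neural markers had 1 higher and 1 lower of 9 (the same adjusted over the list alone, adjusted p = 0.693). Y-linked genes had 1 lower of 7, Uty (1 adjusted over the list alone, adjusted p = 0.619), and X-inactivation genes none of 7 (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.967). Median, mean and test differed in sign for early gonad factors, retinoic acid genes, other patterning factors and X-inactivation genes.

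By limma, 4326 of 18193 genes changed over both sexes, 2445 upward and 1881 downward, 277 and 326 of them at least 2-fold. Repeated quantile normalization gave 2235 upward and 2211 downward, centring on array medians 2537 and 1690 and the mean of all probe sets 2060 and 1925, so the excess of increases depended on the processing. Genotype and any unrecorded batch that followed it cannot be told apart in this design.

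**Figure D4:**
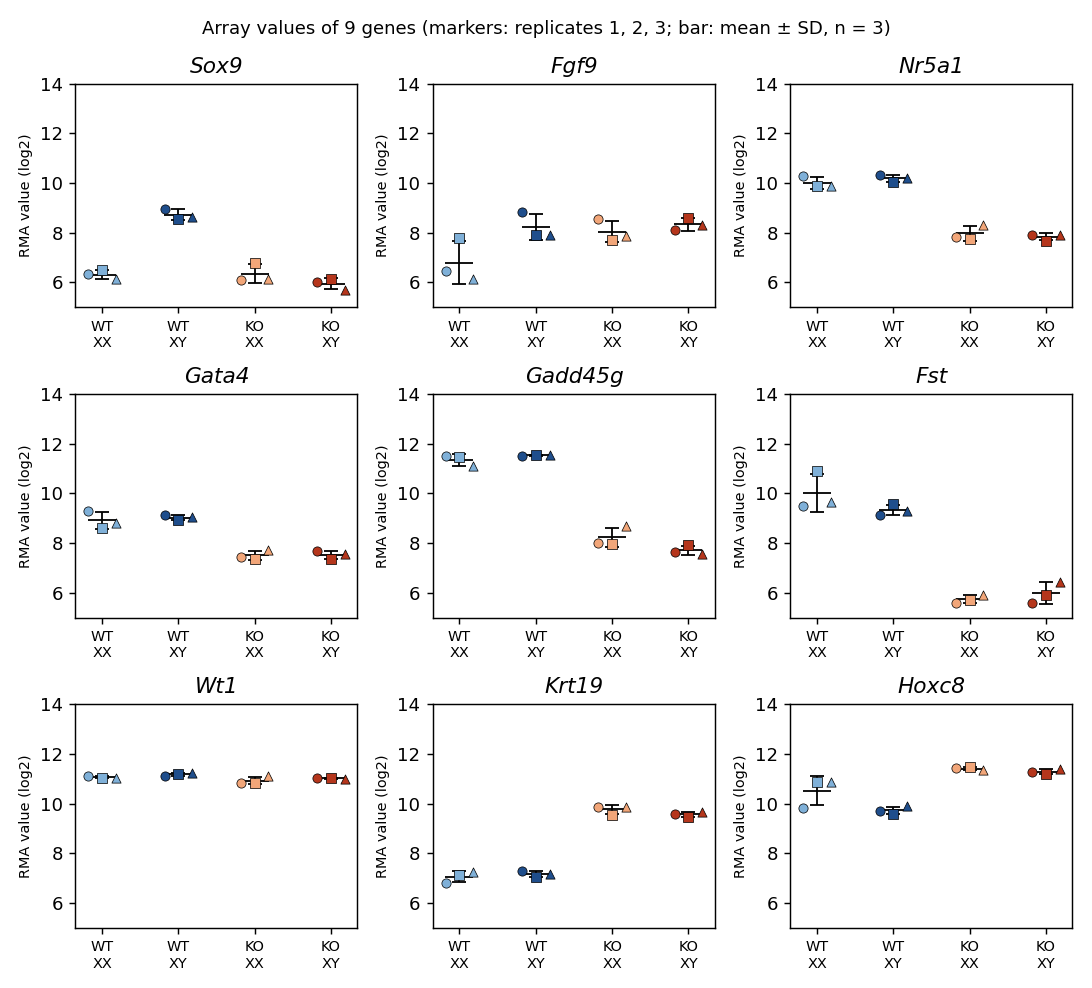
Array values (log2 RMA) of 9 genes in the 4 groups, with a marker per replicate and a bar at the mean ± SD of 3 pools. Sox9 stands at 8.72 in WT XY and between 5.95 and 6.35 in the other groups, and Wt1 lies near the same level in all 4.

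Between WT XY and WT XX gonads, a comparison that shows how far the sexes had diverged, Sox9 was higher in XY by 2.4 ± 0.18 (adjusted p = 7.50e-06), with every XY array above every XX array. Mmd2, a gene of early Sertoli cells, was higher by 1.81 ± 0.29 (adjusted p = 0.0359). The Mmd2 call ended without any of KO XX replicates 2 and 3, KO XY replicates 1, 2 and 3, WT XX replicates 2 and 3 and WT XY replicate 3, at up to adjusted p = 0.259, in a range from 0.00461 to 0.534 over the alternatives. The Y-linked Kdm5d, Eif2s3y, Uty and Uba1y were higher by 6.37 ± 0.17, 6.30 ± 0.15, 4.62 ± 0.13 and 3.62 ± 0.15, and Xist lower, with -6.61 ± 0.11. The remaining genes, named after their values were seen, were Map3k21 (1.78), Cnga1 (1.36), the X-linked Hccs (1.30) and Rnase1 (1.14). With single arrays left out the call ended in 10 of 12 cases for Map3k21, 9 for Cnga1 and 7 for Rnase1, at up to adjusted p = 0.259, and in none for Hccs.

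The testis-pathway list was higher in WT XY, with 2 of 22 members past the threshold and 8 adjusted over the list alone (7 higher and 2 lower past the threshold without WT XX replicate 1; adjusted p = 3.42e-05, and adjusted p = 0.179 with an estimated correlation). Y-linked genes were higher in 4 of 7 cases (the same adjusted over the list alone, adjusted p = 2.54e-22, and adjusted p = 0.000307 with an estimated correlation). X-inactivation genes were lower in 1 of 7 (3 adjusted over the list alone, 4 without WT XX replicate 1, adjusted p = 3.66e-09, and adjusted p = 0.00221 with an estimated correlation). By limma, 11 genes differed, 10 higher in XY and 1 lower, with 1899 at unadjusted p under 0.05. Without WT XX replicate 1 the number was 1876 (901 higher and 975 lower), and without KO XY replicate 1 or 2 it was 7. The 1876 genes rest on WT XX replicates 2 and 3, which lay apart from all other arrays on the second principal component. They need not be sex differences.

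In KO gonads the same comparison found sex-chromosome genes only, among those that passed. Eif2s3y was higher in XY by 6.23 ± 0.15, Kdm5d by 6.16 ± 0.17, Uba1y by 3.93 ± 0.15 and Uty by 3.64 ± 0.13, and Xist was lower, with -6.85 ± 0.11. The X-linked demethylase gene Kdm6a, which escapes X inactivation, had -0.86 ± 0.13 (adjusted p = 0.0221). The Kdm6a call ended without any of KO XX replicates 2 and 3, KO XY replicates 1 and 2 and WT XY replicates 2 and 3, at up to adjusted p = 0.133, in a range from 0.0111 to 0.247 over the alternatives. Sox9 had -0.39 ± 0.18 (adjusted p = 0.50) and Mmd2 -0.41 ± 0.29 (adjusted p = 0.627).

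Y-linked genes were higher in 4 of 7 cases in KO XY (the same adjusted over the list alone, adjusted p = 7.77e-21, and adjusted p = 0.000397 with an estimated correlation). X-inactivation genes were lower in 2 of 7 (6 adjusted over the list alone, adjusted p = 4.51e-13, and adjusted p = 0.000606 with an estimated correlation). Erythroid genes were lower as a list with no member past the threshold (4 adjusted over the list alone), with adjusted p = 0.000127, adjusted p = 0.444 with an estimated correlation, adjusted p = 0.0604 without KO XX replicate 2 and adjusted p = 0.0588 with the RNA-integrity covariate. Proliferation genes were lower as a list with no member past either threshold, the second adjusted over the list alone (adjusted p = 0.000789, and adjusted p = 0.444 with an estimated correlation). By limma, 6 genes differed, 4 higher and 2 lower, with 1822 at unadjusted p under 0.05. The Gapdh difference was higher in KO XY than in KO XX by 0.867 (exact permutation p = 0.1, the smallest possible), and 11 genes passed with it as a covariate.

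The interaction asked whether the loss of Cbx2 acted differently in XY and XX gonads. Sox9 was the gene that passed, with a KO effect in XY minus that in XX of -2.80 ± 0.26 (adjusted p = 0.000576). It stood at 8.72 ± 0.22 in WT XY, 6.32 ± 0.17 in WT XX, 5.95 ± 0.23 in KO XY and 6.35 ± 0.39 in KO XX. Cbln4 had -1.69 (adjusted p = 0.553) and Mmd2 -2.21 (adjusted p = 0.391). Without WT XX replicate 1 Cbln4 passed by limma (-2.04, adjusted p = 0.0190). Uty fell in XY, with a KO minus WT value of -1.09 ± 0.13 (adjusted p = 3.62e-05), with -0.96 on a second probe set that passed and -0.32 and -0.15 on others that did not. Uty did not pass in the interaction. Its XX means (3.52 in KO and 3.63 in WT) are background for a Y-linked gene, so XX offers no KO effect to compare.

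The testis-pathway list was lower in the interaction, with 1 of 22 members past the threshold and 6 adjusted over the list alone (adjusted p = 0.000548, adjusted p = 0.379 with an estimated correlation, and adjusted p = 0.132 with the RNA-integrity covariate). By limma, 1 gene passed, with 1174 at unadjusted p under 0.05. With the RNA-integrity covariate the Sox9 value was -2.55 ± 0.36 (adjusted p = 0.0961, in a range from 0.000105 to 0.0961 over the alternatives) and 0 genes passed, with 1266 at unadjusted p under 0.05. Without WT XX replicate 1, 10 genes passed, and without KO XX replicate 2 or KO XY replicate 1 the number was 2.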

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

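The tests of the share of gonadal cells, of RNA integrity, batch and exchanged labels behind the knockout effect, of the sex of WT XX replicate 1 and of single arrays and batch behind Sox9 were chosen only after the result was seen. Sox9 stood out because the knockout changed it differently in the sexes, by -2.80 on the log2 scale in XY minus XX. The testis-pathway list did so too (adjusted p = 0.000548, kept with each of the 12 arrays left out in turn), but not with an estimated correlation (adjusted p = 0.379) or with the RNA-integrity covariate (adjusted p = 0.132). The proliferation list was lower in the same test (adjusted p = 0.00117, adjusted p = 0.558 with an estimated correlation, 0 of 27 members past the threshold and 0 adjusted over the list alone by limma), but not without WT XX replicate 1 (adjusted p = 0.0894). The coelomic epithelium list was lower (adjusted p = 0.0329, adjusted p = 0.379 with an estimated correlation, 0 of 10 members adjusted over the list alone). That call was lost without any of KO XX replicates 2 and 3, KO XY replicates 1 and 2, WT XX replicates 1 and 2 and WT XY replicate 2, at up to adjusted p = 0.106, and with the RNA-integrity covariate (adjusted p = 0.129). The erythroid list was lower (adjusted p = 0.0142, adjusted p = 0.565 with an estimated correlation, 0 of 11 members adjusted over the list alone), but not without KO XX replicate 2, KO XY replicate 2 or WT XX replicate 1, at up to adjusted p = 0.290, nor with the RNA-integrity covariate (adjusted p = 0.0934). Among 10092 probe sets with no gene or several genes, which the gene comparisons left out, 1088 changed between KO and WT over both sexes, 694 upward and 394 downward. Groups of 3 arrays were too small for a search for single outlying arrays.

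The first pattern is the broad difference between KO and WT. A lower share of gonadal cells in the captured KO tissue was predicted to raise the markers of all other cell types alike. The array means of 16 endothelial genes changed by -0.71 ± 0.14 and of 13 macrophage genes by 0.44 ± 0.12, apart by -1.155 ± 0.08 (SE, each exact permutation p = 0.005 over arrays, the smallest possible). As lists against all genes neither passed camera with an estimated correlation (adjusted p = 0.219 and adjusted p = 0.440). Of the brightest markers, chosen after their values were seen, the endothelial Kdr had 0.15 ± 0.13 (adjusted p = 0.471), Mmrn2 -0.72 ± 0.34 (adjusted p = 0.143) and Sox17 -1.35 ± 0.16, and the macrophage Csf1r had 0.75 ± 0.18. The opposite moves of the sets argue against a lower share that raises all other cell types alike. They do not decide on a share lost to a single neighbouring tissue, which need not raise both sets. Coelomic epithelium markers rose as a list over both sexes (camera adjusted p = 0.00109), and mesonephros markers did not (camera adjusted p = 0.693). A lower gonadal share and a change in macrophages or vessels themselves therefore stay open. RNA integrity differed between KO and WT in XY and not in the same direction in XX. Yet the effects in both sexes correlated at 0.825 across genes, which argues against RNA integrity as the whole cause. With it as a covariate the XY count dropped from 2421 to 780, while the XX count rose from 2493 to 3175. The Gapdh difference was highest in KO XY (4.91, against 4.05 to 4.31 in the other groups), so the covariate overlaps with that group. The drop therefore does not tell how many XY calls rest on RNA integrity. A batch that follows genotype cannot be told apart from genotype, since the labels give no batch and the leading component, with 53.3% of the variance, separates the genotypes. Exchanged genotype labels would turn every KO direction. Cbx2 does not settle this, since its signal was higher by 0.633 ± 0.08 in arrays labelled KO. It lay over 1 log2 unit above the median gene in both genotypes, so it shows a loss in neither. The XY rise of Sox9, seen only in arrays labelled WT, argues against an exchange. The other testis-pathway genes had mean XY minus XX differences of 0.41 in WT and -0.02 in KO. That list's camera call in the interaction did not hold with an estimated correlation (adjusted p = 0.379). A biological explanation, a loss of Cbx2 that changes the gonadal cells themselves, was not tested and stays open.

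The second pattern is WT XX replicate 1, whose values lay nearer to WT XY than to its own group. A wrong sex of the pool is argued against by its Eif2s3y, which lay 6.235 below the lowest XY array. A hybridisation difference (its spike-in level was -1.05 relative to replicates 2 and 3) predicted its difference across genes with a correlation of 0.276, and RNA integrity with 0.281. Both lie between the bounds set beforehand (0.1 and 0.3), so either could contribute and neither is settled. A difference in stage or cell make-up, of this pool or of replicates 2 and 3, is a candidate explanation that was not tested. Replicates 2 and 3 lay apart from all other arrays on the second principal component, at 28.46 and 29.2, with the next highest array at 11.64. Which of the WT XX pools deviate is therefore not settled.

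The third pattern is Sox9, higher in XY than in XX in WT and not in KO, and its interaction of -2.80 ± 0.26 argues against a batch that follows genotype and shifts both sexes alike, which predicts 0. With the RNA-integrity covariate the interaction moved from -2.80 ± 0.26 to -2.545 ± 0.36 and its adjusted p from 0.000576 to 0.0961, in a range from 0.000105 to 0.0961 over the alternatives. The call ended mainly because the error grew with the covariate in the model, while the estimate stayed more than 2 standard errors below -1, which argues against RNA integrity as the whole cause. Leaving out each of the 12 arrays in turn brought the Sox9 value no nearer to 0 than -2.573 (highest adjusted p = 0.00344), which argues against a single deviating array. Exchanged genotype labels would leave wild-type XY gonads without the rise of Sox9, which argues against an exchange. A batch that differs between all 4 groups, a loss of signal hidden by the low XX level (6.32 in WT) and a need for Cbx2 in the XY rise of Sox9, which was not tested, stay open.

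Other splits of the arrays were compared with the real groups. For KO against WT over both sexes 1 of 100 splits, the real grouping, gave as many genes (4326, with 633 as the highest other), so chance is unlikely to give this count. The splits do not address a batch that follows genotype. For the interaction 10 of 100 splits gave as many as the 1 real gene (highest other 1), and the other 90 gave none. In each of those 10 splits the WT arrays kept their sexes and the called gene was Sox9. These splits exchange sex labels within genotype, and Sox9 did not differ between the sexes in KO. Exchanging KO labels could therefore leave the call in place, so this share does not decide on chance. The comparisons of 3 against 3 allow 10 splits, too few for a share under 0.05. In these 1 of 10 splits, the real one, gave as many genes, with 2421 and a highest other of 0 in XY, 2493 and 8 in XX, 11 and 0 between the sexes in WT and 6 and 0 in KO.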

How the results depend on the processing

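The RNA-integrity and spike-in covariates were chosen only after the result was seen. No direction of a named gene's call turned under any alternative: of 4243 repeats of 336 calls under other settings 3916 were kept and 327 lost, and of 4032 repeats with an array left out 3740 were kept and 292 lost. Many of these repeats could not turn a direction, since the estimate stayed the same. This holds for other thresholds, the low filter, another variance prior, fits of the compared groups alone and arrays outside the contrast. Tests by probe set used the same probe set for each named gene. A threshold of 0.10 kept every call by construction. Counts in the order XY, XX, WT sexes, KO sexes, interaction and both genotype effects averaged were 2421, 2493, 11, 6, 1 and 4326. Tested by probe set, with 45037 in place of 18193 tests, they were 4003, 4213, 25, 17, 3 and 7910. With array weights the XY count was 4406, that for the WT sexes 1191 and the interaction 3. WT XX replicate 1 had the lowest weight, 0.303. A required log2 fold change of 1 left 680, 619 and 603 genes in XY, XX and both, by construction. Fits of the compared groups alone gave 3802 in XY, 1532 in XX and 7 between WT sexes. The RNA-integrity covariate gave 780 in XY, 3175 in XX, 11 between KO sexes and 0 for the interaction by limma. In that interaction 1266 genes had an unadjusted p under 0.05, and Sox9 had an unadjusted p of 5.28e-06. The spike-in covariate gave 13 between KO sexes and 2 for the interaction. The cause was not tested, except where the setting itself changes the number of tests or the threshold. With single arrays left out, which assumes a reduced group varies like the others, counts ran from 1598 (without WT XY replicate 1) to 3397 (without WT XX replicate 1) in XY, 1881 to 2440 in XX, 7 (without KO XY replicate 1 or 2) to 1876 (without WT XX replicate 1) between WT sexes, 5 to 9 between KO sexes, 1 to 10 (without WT XX replicate 1, and 2 without KO XX replicate 2 or KO XY replicate 1) for the interaction and 3486 to 4405 over both. Of the 23 lists 8 passed over both sexes, 3 with an estimated correlation, 14 by fry, which tests each list by itself, and 6 to 10 with single arrays left out. With the RNA-integrity covariate 4 list calls ended, for testis-pathway, coelomic epithelium and erythroid genes in the interaction and erythroid genes between KO sexes. It added 5, for proliferation, germ cell and erythroid genes in XY, PRC2 subunits in XX and germ cell genes over both. A replicate block gave 2565, 2498, 12, 6, 1 and 4423 genes and 8 lists, and the replicate numbers do not pair the arrays. Repeated normalization, centring, the low filter, another variance prior, a threshold of 0.10 and the mean of probe sets kept all counts within 1.5 times, but repeated quantile normalization brought the share of increases from 60.6% to 51.1% in XX and from 56.5% to 50.3% over both sexes, and the mean of probe sets to 55% and 51.7%. The scale alternative for linear values was not run, since the values were log2. Genes at background, such as Sry, whose XY signal matched that in XX, could not show a difference.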

Other observations

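All tests in this part, on gene families and on clusters, were chosen only after the result was seen. Among 225 families of genes sharing a symbol stem, each with at least 10 measured members, zinc finger genes named Zfp were higher in KO over both sexes in 95 of 336 cases and lower in 16 (camera adjusted p = 0.00239). The Adamts proteases of the matrix (8 higher and 1 lower of 15), the collagens (19 and 7 of 42), the beta protocadherins (9 and 0 of 22) and the Zkscan zinc finger genes (7 and 0 of 10) were higher as well, each with adjusted p = 0.0119. Subunits of the mitochondrial ribosome were lower, with 2 higher and 10 lower of 47 Mrpl genes (adjusted p = 0.0140) and 0 higher and 9 lower of 29 Mrps genes (adjusted p = 0.0231). For these families the result was adjusted p = 0.980 or 0.982 with an estimated correlation. Between the sexes 2 families passed camera in WT and 11 in KO, and none with an estimated correlation. Each of these families had 0 members past the threshold. Mrpl genes, with a median of -0.182 in KO minus WT, had an XY minus XX median of 0.210 in WT (camera adjusted p = 0.00666) and 0.174 in KO (adjusted p = 0.0117). In each of the 2 genotypes 0 of 47 members passed the threshold. With an estimated correlation the results were adjusted p = 0.994 in WT and adjusted p = 0.854 in KO.

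The change of the 33 Hox genes over both sexes, of which 13 rose and whose list did not pass camera with an estimated correlation (adjusted p = 0.219), was uneven between the clusters (F ratio 3.56, permutation p = 0.0277). Mean changes were 0.61 ± 0.68 over 9 Hoxa genes and 0.83 ± 0.51 over 7 Hoxc genes, against 0.18 ± 0.31 over 9 Hoxb and 0.13 ± 0.41 over 8 Hoxd genes (SD). This is consistent with a response that differs by cluster, although neighbouring genes are not independent and a batch following genotype stays open.

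The mean XY minus XX difference over the 22 testis-pathway genes was 0.50 ± 0.74 in WT and -0.04 ± 0.27 in KO (SD over genes), lower in KO for 14 genes (permutation p = 0.00432 over signs, with genes treated as independent). Without Sox9 the means were 0.41 and -0.02. The sex difference of this list may depend on the genotype as labelled, as a hypothesis found and tested on the same data, although its camera call in the interaction ended with the RNA-integrity covariate (adjusted p = 0.132) and with an estimated correlation (adjusted p = 0.379). Across 18179 genes outside the sex-chromosome lists, the sex differences in WT and KO, which share no array, correlated at r = 0.247 and rho = 0.184, although genes are not independent replicates.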
